A study of Zea mays with 15 samples.

How the data were processed

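RNA from the growth zone of maize leaf 4 (inbred line B73) was sequenced after stranded mRNA library preparation, per the labels' protocols. The plants grew outdoors under plastic filters. Per the labels, the control filter let 0.35 W/m2 of UV-B pass and the other filter 1.5 W/m2, with 8 W/m2 of UV-A under both (means at noon). Leaves were taken 3 days after emergence and their base was divided into 10-mm segments. Zone 1 is 0 to 1 cm from the leaf base, zone 2 is 1 to 2 cm and zone 3 is 2 to 3 cm. The labels gave 15 libraries in 6 groups, with their replicate numbers.

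The authors deposited 1 table for the series with counts of total and unique reads per transcript and RPKM values, per the file headers. Unique reads are those assigned to 1 transcript only. They made up 44.5% to 47.9% of the total counts of a library. By this definition, reads shared by transcripts of 1 gene are not unique either. Tests with unique reads therefore also have lower depth, and a change under them need not come from reads shared between genes. The RPKM values deposited by the authors were not used in any test. The aligner, its settings and the genome build are not given in the sources used here. The table also held 21 value columns of 3 libraries whose names match no sample of the labels, and these were not used. Gene coordinates are printed as the deposited table gives them, on a build that it does not name.

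Total read counts of the 62892 transcripts were summed to 39145 genes by the gene part of their identifiers. Symbols came from the RefSeq annotation of Zm-B73-REFERENCE-NAM-5.0, used for names only. By synonym, 18842 genes matched a record, 521 of them more than 1 record, and 2722 genes had a name. Families with near-identical members, such as histones, tubulins, ribosomal proteins and benzoxazinoid genes, can share reads, so single members of these families are uncertain.

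Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, using filterByExpr over the 6 groups (23552 genes kept), TMM scaling and the two-sided quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The UV-B effect over all zones came from an additive model of zone and treatment. All other comparisons were contrasts of a model with 6 groups. Standard errors (SE) of log2 fold changes were derived from the F statistic. UV-B zone 3 replicate 1 held only 728 reads. It stayed in the fits, whose design was set before the data were examined, and each count of genes is also given without it (23899 genes tested). Means and SD of CPM use the 14 libraries with more than 1000000 reads. CPM here are the reads of a gene over 1000000 reads of all genes, without TMM scaling.

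Before the data were examined, themes for gene lists were set for growth, cell division, light, UV-B, hormones, defence, stress and tissue markers. The themes were then filled by symbol into 41 lists with 678 members. That was done after the table was seen and before any test, and it split or added lists for cell number regulators, aquaporins, tubulins, leaf polarity, auxin response factors and jasmonate. Lists were tested against all other genes with camera of limma 3.58.1 on log2 CPM, two-sided, with a preset correlation of 0.01, and adjusted over the 41 lists within a comparison. In these tests all 15 libraries had equal weight, UV-B zone 3 replicate 1 with its 728 reads among them. Results without it are named as such. Medians of log2 changes printed with a list test come from edgeR. Camera with an estimated correlation and fry served as alternatives.

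Genes to be named followed a rule set before the data were examined. For 4 comparisons (UV-B over all zones, UV-B in zone 2, UV-B in zone 3, and control zone 3 against zone 1) it took up to 6 rising and 6 falling genes with the largest changes. These had to have a name, an adjusted p under 0.05, a group mean of at least 10 CPM and no overlap between the groups compared. For UV-B in zone 1 and for the interaction it took up to 3 in each direction, in zone 1 without the condition on overlap. From lists with a called member it took up to 3 members with the smallest adjusted p, and from other lists up to 2 with the highest expression. The called UV-B genes have no informative name and fell outside this rule, so they were chosen after their values were seen.

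Alternatives were scaling by DESeq2 size factors, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, fits of the compared groups alone, a stricter threshold, a replicate block, leaving out each library, and other designs for the joint UV-B effect. Alternatives chosen after seeing the data were unique reads, thinning to 1673416 reads per library, voom over the usable libraries with and without a correlation of same-numbered libraries, surrogate variables from sva 3.50.0, a position covariate, and list tests for zone 1 and for the interaction. The scripts were tested on simulated data. For UV-B over all zones, 56.1% of genes simulated at a 2-fold change and 85% at 4-fold were recovered among 22957 genes. For UV-B in zone 2 these shares were 6.12% and 61% among 22966 genes, and for UV-B in zone 3 they were 5.15% and 43.9% among 22921 genes. For control zone 3 against zone 1 they were 12.5% and 67.3% among 22533 genes. In the order given, these simulations also called 6, 9, 3 and 6 unchanged genes. Simulated libraries were drawn independently, without an effect of replicate number. Real libraries of the same number and treatment correlated (0.470), so these shares need not hold for the real data.

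A position of each library along the leaf axis was computed over 12263 genes that differed between control zones 1 and 3, with 0 as the mean of control zone 1 and 1 as that of control zone 3. The labels say that the experiment was run 3 times in 1 summer but do not link replicate numbers to these runs, or say whether libraries came from separate plants or pools. P-values therefore measure the spread between these libraries. Segments of the same number and treatment may come from the same leaves, in which case the zones of a treatment are not independent and the joint UV-B test gives p-values that are too small. Depth fell from zone 1 to zone 3, so depth and zone are confounded.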

Results

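Transcripts were counted in 3 adjacent segments of the growing maize leaf, from plants under a filter that removed most solar UV-B (control) and plants under one that let it pass (UV-B). Control zones 1, 2 and 3 had 3, 2 and 3 libraries, and UV-B zones 1, 2 and 3 had 1, 3 and 3. Depth ranged from 11147867 to 17923081 reads in control zone 1, from 4568682 to 7840247 in control zone 2 and from 2007679 to 6222019 in control zone 3. The UV-B zone 1 library had 19221143 reads, and the UV-B zone 2 libraries had 9471340 to 13887955. UV-B zone 3 replicates 2 and 3 had 4665312 and 1673416 reads, while replicate 1 had 728 reads and 547 detected genes.

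Within control leaves, the question was which genes differ along the first 3 cm from the base. Growth-regulating factors and genes of DNA replication, mitosis and DNA repair were lower in zone 3 than in zone 1, and genes of photosynthesis, water channels and expansins were higher, by list tests of which none held with an estimated correlation between genes (adjusted p = 0.931 for each). GIF1 (GRMZM2G180246), a coactivator that partners growth-regulating factors, fell from 74.4 ± 16.3 CPM (SD, n = 3) in zone 1 to 7.75 ± 2.66 (n = 2) in zone 2 and 0.640 ± 0.140 (n = 3) in zone 3. The YABBY transcription factor gene yab14 (GRMZM2G005353) fell from 29.1 ± 9.88 to 0.107 ± 0.186 CPM between zones 1 and 3. PIP2-4 (GRMZM2G154628), a plasma membrane aquaporin gene, rose from 0.543 ± 0.182 to 182 ± 92.3 CPM over the same distance. By edgeR's quasi-likelihood test, 12153 of 23552 genes differed between control zones 3 and 1 at an adjusted p under 0.05, 6061 higher and 6092 lower in zone 3. Without UV-B zone 3 replicate 1 the count was 12263, of which 11764 were shared.

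By the naming rule, the largest falls from zone 1 to zone 3 were those of yab14, which had 2 reads in all of control zone 3 and so gets no fold, and of GIF1 (log2 fold change -6.66 ± 0.38 SE, adjusted p = 4.11e-07 by edgeR). Next came argonaute6 (GRMZM2G347402), with 32.8 ± 12.3 CPM in zone 1 and 0.313 ± 0.411 in zone 3, and PARP2 (GRMZM2G099231), with a log2 change of -6.24 ± 1.09. The 2 other genes were yab10 (-5.01 ± 0.71) and EREB161 (-4.96 ± 0.51). The largest rises were in genes with almost no reads in zone 1, for which levels are given in place of folds. The glucosidase gene glu2 had 0.0186 ± 0.0322 CPM in zone 1 and 224 ± 41.8 in zone 3. MYB61 and Myb20, both MYB transcription factor genes, had no reads in zone 1 and reached 65.9 ± 11 and 32.9 ± 9.02 CPM in zone 3. The aquaporin genes PIP2-3 and TIP2-1 had 0.0299 ± 0.0518 and 0.0744 ± 0.129 CPM in zone 1, against 48.6 ± 26.6 and 113 ± 87.5 in zone 3. For kin1 the values were 0.0299 ± 0.0518 and 22.0 ± 37.0 CPM, and its call ended without control zone 3 replicate 1 (log2 change 4.31, edgeR adjusted p = 0.0562) and by limma-voom (adjusted p = 0.126).

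Of 18 measured growth-regulating factors and their coactivators, 15 fell from zone 1 to zone 3 and 1 rose, with the same counts when adjusted over the list alone (median log2 change -2.48, camera adjusted p = 8.15e-08). With an estimated correlation neither this list nor any other of the 10 that passed between control zones 3 and 1 held (adjusted p = 0.931 for each). GRF12 and GRF13 had log2 changes of -2.56 ± 0.28 and -2.82 ± 0.32. Of 17 DNA replication genes, 15 fell and 1 rose (median -2.29, camera adjusted p = 4.03e-05). They included RNRL2, a ribonucleotide reductase gene (-3.21 ± 0.32), DP2, a partner of E2F factors (-2.69 ± 0.24), and RBR3, a retinoblastoma-related gene (-4.14 ± 0.47). Of 25 mitosis genes, 19 fell, and adjusted over the list alone 19 fell and 2 rose (median -2.58, camera adjusted p = 5.98e-06), among them cyclin11 (-4.59 ± 0.40) and krp11 (-4.04 ± 0.38), the latter a kinesin-related gene by its synonyms. The counts for DNA replication, DNA repair and auxin response factors were the same adjusted over the list alone. Of 8 DNA repair genes, 7 fell (median -2.30, camera adjusted p = 0.000434), among them mre11A (-3.05 ± 0.26) and MSH1 (-3.67 ± 0.46). Of 16 auxin response factors, 14 fell and 1 rose (median -1.54, camera adjusted p = 0.0252), with ARF4 at -4.24 ± 0.37 and ARF30 at -2.36 ± 0.24. Of 32 histone genes, 4 fell over all genes tested and 0 when adjusted over the list alone (median -1.11, camera adjusted p = 0.0273).

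All 16 measured genes of the light reactions rose from zone 1 to zone 3 (median log2 change 4.59, camera adjusted p = 3.39e-09, and 0.931 with an estimated correlation, as for the other lists here). The photosystem I gene psad1 rose by 5.54 ± 0.47, and the ferredoxin gene FDX1 went from 20.6 ± 8.37 to 497 ± 54.8 CPM. Of 8 genes of C4 photosynthesis, 6 rose (median 3.89, camera adjusted p = 0.000434), including ssu1, a Rubisco small subunit gene (5.55 ± 0.61), and mdh6, a malate dehydrogenase gene (3.40 ± 0.31). Of 14 aquaporins, 11 rose (median 2.63, camera adjusted p = 5.98e-06). Of 11 expansins, which loosen cell walls, 7 rose (median 2.25, camera adjusted p = 0.00478), among them expB4, from 3.16 ± 0.459 to 70.1 ± 24.0 CPM. The counts of rising genes in these 4 lists were the same when adjusted over the list alone. All 10 lists passed without UV-B zone 3 replicate 1, and 13 in total.

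Adjacent zones were compared in the same way. Between control zones 2 and 1, 1860 genes differed by edgeR, 1413 higher and 447 lower in zone 2, and between control zones 3 and 2, 3109 differed, 1359 higher and 1750 lower in zone 3. These counts were 1990 and 3184 without UV-B zone 3 replicate 1. Under UV-B, 1708 genes differed between zones 3 and 2, 819 higher and 889 lower, and 1637 without that library. DESeq2 size factors shift the median log2 change of all genes by 0.14 in that last comparison and by less than 0.1 in the others. RNRL2 had 139 ± 17.1, 61.0 ± 9.17 and 14.3 ± 3.71 CPM in control zones 1, 2 and 3, and ssu1 had 8.11 ± 4.98, 38.7 ± 0.647 and 357 ± 104. The counts between adjacent zones rest on few libraries. Leaving out any of the 5 libraries of control zones 1 and 2 took the first to 946, 1146 and 958 (control zone 1 replicates 1, 2 and 3) and to 827 and 1029 (control zone 2 replicates 2 and 3). Leaving out control zone 2 replicate 3, control zone 3 replicate 3 or control zone 3 replicate 1 took the next to 750, 1231 or 1689. Without control zone 2 replicate 3 the order of the 2 control counts was therefore the opposite one (1029 and 750). Leaving out UV-B zone 3 replicate 3 or UV-B zone 2 replicate 2 took the last to 149 or 486.

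On the zone axis, control libraries averaged 0.449 ± 0.107 (SD, n = 2) in zone 2 against 0 in zone 1 and 1 in zone 3. UV-B libraries lay at 0.0763 in zone 1 (n = 1), 0.579 ± 0.118 in zone 2 (n = 3) and 1.03 ± 0.0809 in zone 3 (n = 2). The summed difference between treatments was 0.233 (two-sided exact permutation p = 0.1075 over 400 arrangements within zones). Control libraries of zones 1 and 3 set the axis, and the arrangements break up same-numbered libraries, which correlated (0.470). This p-value is therefore only a guide. Principal component 1 held 70.2% of the variance over 13820 genes.

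**Figure D1:**
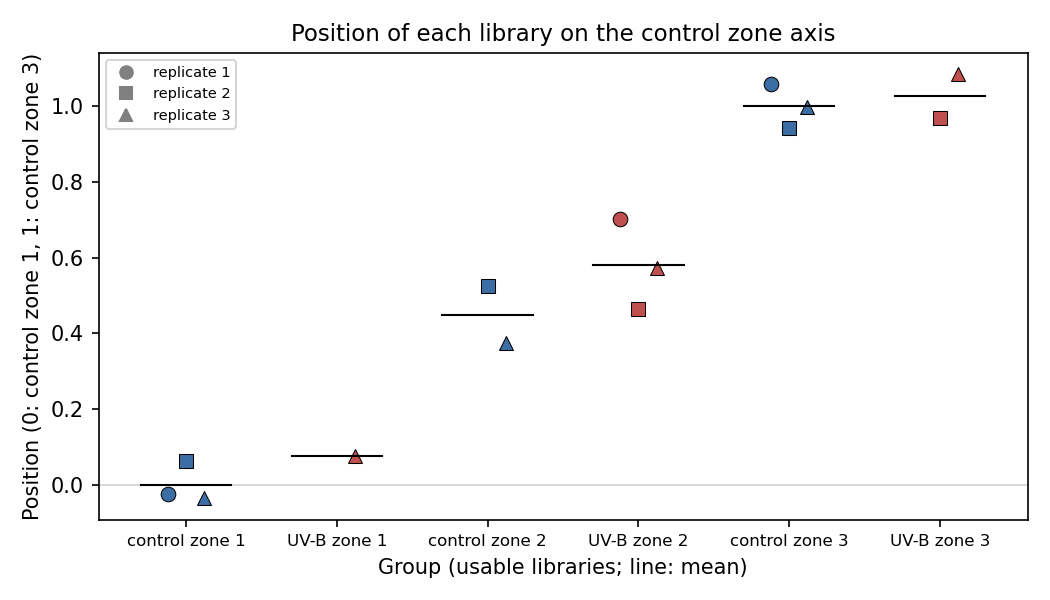
Position of each library along the zone axis (vertical, 0 for the mean of control zone 1 and 1 for that of control zone 3) by group, with replicate number as marker, control in blue, UV-B in red and the mean of the usable libraries as a line. UV-B zone 2 libraries averaged 0.579 and control zone 2 libraries 0.449.

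The main question was which genes differ between UV-B and control leaves. Over the 3 zones together, 14 of 23552 genes differed by edgeR, 6 higher and 8 lower under UV-B, and none has an informative name. Libraries of the same number and treatment correlated (0.470). Over the 14 usable libraries, limma-voom called 4 genes without this correlation and 1 with it. The clearest was GRMZM2G036640 (chromosome 1, 264587455 to 264589878). It had 20.5 ± 1.45 (SD, n = 3), 17.8 ± 3.33 (n = 2) and 17 ± 3.08 (n = 3) CPM in control zones 1, 2 and 3, and 71.9 (n = 1), 57.7 ± 1.51 (n = 3) and 46.8 ± 4.00 (n = 2) under UV-B. It was higher in 6 of 6 usable UV-B libraries than in all 8 controls (log2 fold change 1.62 ± 0.12 SE, adjusted p = 7.31e-06). With unique reads alone its log2 change was 1.37 and the call ended (edgeR adjusted p = 0.307). Over all alternatives its adjusted p ranged from 2.43e-36 by DESeq2 to that value. GRMZM2G445139 (chromosome 1, 253459348 to 253464451) had 0, 0.109 ± 0.155 and 0.118 ± 0.104 CPM in control zones 1, 2 and 3 and 12.6, 5.08 ± 2.19 and 5.69 ± 0.441 under UV-B (adjusted p = 1.96e-05). Its adjusted p by limma-voom over the 14 usable libraries was 0.00133, and 0.137 with the correlation of same-numbered libraries, which ended its call at a log2 change of 6. GRMZM5G877929 had a log2 change of 2.15 ± 0.26 (edgeR adjusted p = 0.00181, and 0.0528 without UV-B zone 1 replicate 3), and GRMZM2G039373 one of 0.86 ± 0.13 (edgeR adjusted p = 0.0136). The GRMZM2G039373 call ended without control zone 3 replicate 2 (adjusted p = 0.0527) or 3 (0.0501), UV-B zone 2 replicate 2 (0.0521), UV-B zone 3 replicate 2 (0.0631) or UV-B zone 1 replicate 3 (0.0528). With the correlation of same-numbered libraries both lost their calls (limma-voom adjusted p = 0.0845 and 0.137) at log2 changes of 2.1 and 0.88, close to those above. These genes were chosen after their values were seen.

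**Figure D2:**
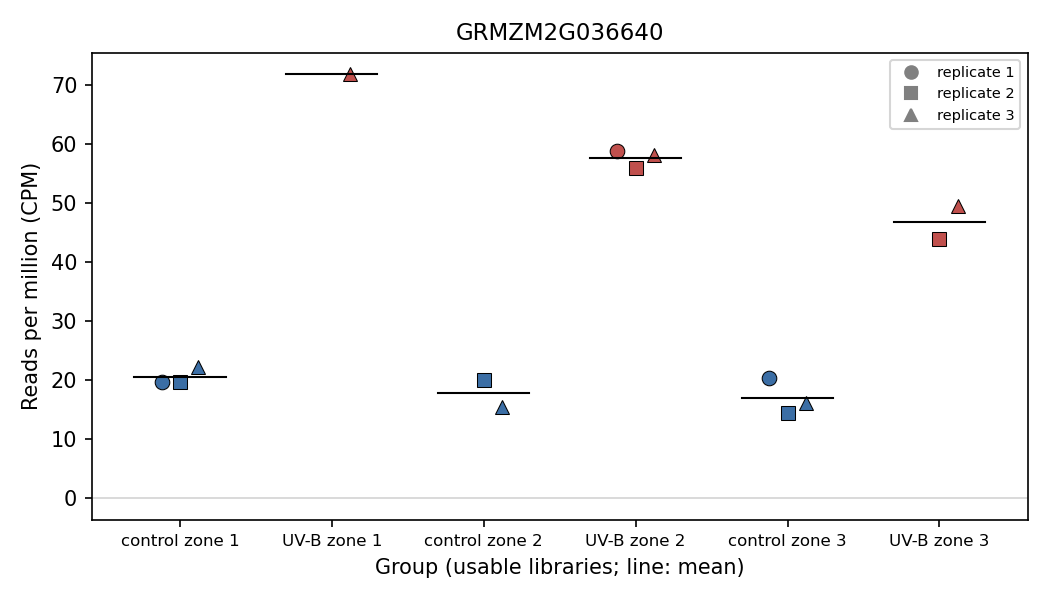
Level of GRMZM2G036640 (vertical, CPM) in each usable library by group, with replicate number as marker, control in blue, UV-B in red and the group mean as a line. The group means lie between 17 and 20.5 in control and between 46.8 and 71.9 under UV-B.

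Of the 14 genes, 6 lie within 21.1 Mb of chromosome 1, from 253459348 to 274578972. The called genes there are 5 of the 6 higher genes (GRMZM2G445139, GRMZM2G039373, GRMZM2G085873, GRMZM2G036640 and GRMZM5G877929) and 1 lower gene (GRMZM2G092433). This span holds 335 of the tested genes. Of the other lower genes, GRMZM2G375487, GRMZM2G419024, GRMZM2G108258 and GRMZM2G373738 were off in control replicate 1 and in all UV-B replicates and on in control replicates 2 and 3. Of the 14, 7 were called without UV-B zone 3 replicate 1 (5 higher, 2 lower, and no others), 5 of them in that span. GRMZM2G092433 lost its call on leaving out any 1 of 12 of the 15 libraries. GRMZM2G036640 and GRMZM2G445139 lost theirs on leaving out 0 of the 15, but each lost it under another alternative, named above. The count was 3 without UV-B zone 1 replicate 3, 4 without UV-B zone 2 replicate 2, 7 without control zone 3 replicate 3, 8 without control zone 1 replicate 3 or control zone 3 replicate 2, and 9 without UV-B zone 3 replicate 2.

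Within single zones few genes differed. In zone 1, the only gene called by edgeR was GRMZM2G445139, also without UV-B zone 3 replicate 1. This rests on a single UV-B library, so that the spread comes from the other groups. GRMZM2G445139 had no reads in control zone 1 and so gets no fold, and its call ended after thinning to equal depth. Leaving out control zone 1 replicate 3 or control zone 2 replicate 3 gave 2 genes. In zone 2, 0 genes differed by edgeR and by edgeR without UV-B zone 3 replicate 1, with 998 at an unadjusted p under 0.05, while DESeq2 called 3 and limma-voom 1. Leaving out UV-B zone 2 replicate 3 gave 2. In zone 3, 1 gene differed, GRMZM2G169927 (chromosome 4, 240039042 to 240048763), which fell from 25.0 ± 5.93 CPM (SD, n = 3) to 3.64 ± 0.919 (n = 2). Its log2 change was -2.74 ± 0.32 (adjusted p = 0.0104, and 0.0487 without UV-B zone 3 replicate 1) in both usable UV-B libraries. The call ended without control zone 3 replicate 2 or 3, or UV-B zone 3 replicate 2 or 3, each of which gave 0 genes, at log2 changes of -2.51 or lower. No gene's UV-B effect differed between zones 3 and 2 by edgeR (0 genes, 489 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom).

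Among gene lists, jasmonate response genes, mostly repressor genes of the TIFY family that jasmonate induces, were higher under UV-B. Over the zones together 0 of 19 members passed over all genes and 9 rose when adjusted over the list alone (median log2 change 0.51, camera adjusted p = 1.20e-10, and 0.991 with an estimated correlation). In zone 2 the median was 0.84 (camera adjusted p = 1.10e-10, and 0.982 with an estimated correlation) and in zone 3 it was 0.51 (camera adjusted p = 0.000288, and 0.947 with an estimated correlation), with 0 members passing in either zone over all genes or adjusted over the list alone. The rise was not shared by the UV-B libraries. The median difference from other control libraries of the zone was 0.888 and 0.817 in UV-B zone 2 replicates 1 and 2 and 0.769 in UV-B zone 3 replicate 2. It was 0.129, 0.00441 and -0.0676 in the replicate 3 libraries of UV-B zones 1, 2 and 3, within the control range of -0.296 to 0.185. In zone 2, jasmonate synthesis genes (median 0.60, camera adjusted p = 0.0197) and defence genes (median 0.85, camera adjusted p = 0.0295) also passed, with 0 members passing over all genes or adjusted over the list alone. Both had adjusted p = 0.982 with an estimated correlation.

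**Figure D3:**
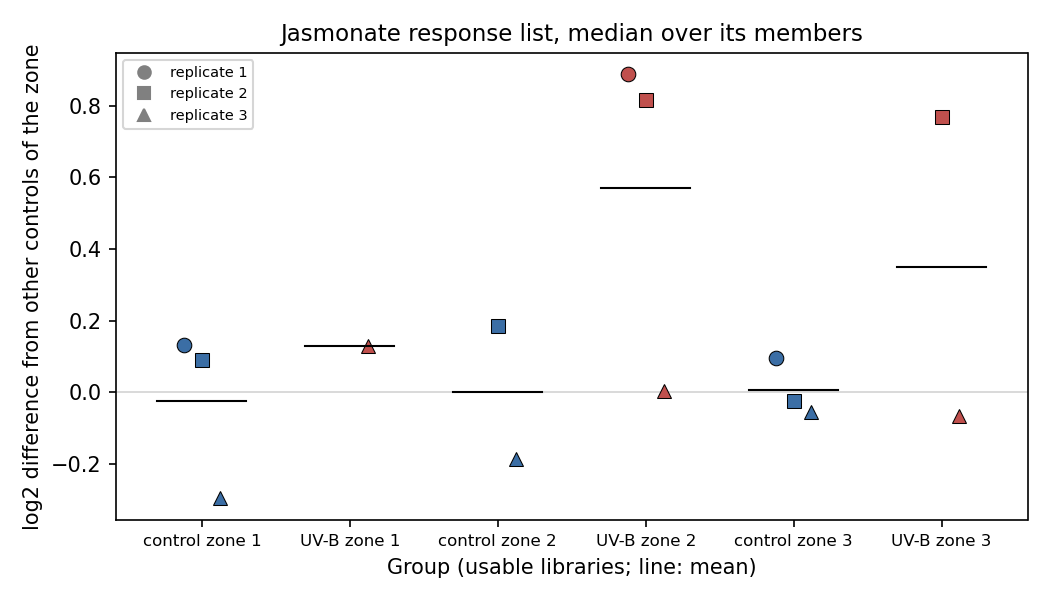
Median over 19 jasmonate response genes of the log2 difference from the other control libraries of the zone (vertical) in each usable library by group, with replicate number as marker, control in blue, UV-B in red and the group mean as a line. UV-B zone 2 replicates 1 and 2 and UV-B zone 3 replicate 2 lie between 0.769 and 0.888, and UV-B replicate 3 libraries between -0.0676 and 0.129.

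Over the zones together, 7 of 41 lists passed, and 0 with an estimated correlation (adjusted p = 0.991 for each of the 7). Beside jasmonate response these were, higher under UV-B, expansins (median 0.36, camera adjusted p = 0.0109), clock genes (0.86, camera adjusted p = 0.0109), KNOX and ligule genes (0.42, camera adjusted p = 0.00305) and secondary wall genes (0.29, camera adjusted p = 0.0400). Lower were DNA replication (median -0.19, camera adjusted p = 0.0109) and heat shock proteins (-0.62, camera adjusted p = 0.00646). None of their members passed over all genes, and 1 KNOX and ligule gene rose when adjusted over the list alone. In all, 12 lists passed without UV-B zone 3 replicate 1, 5 of these 7 among them. The clock genes (camera adjusted p = 0.213) and secondary wall genes (camera adjusted p = 0.330) were lost.

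The clock and heat shock lists also differed between replicate numbers of 1 treatment. The mean log2 CPM of the 4 clock genes was 6.54, 4.02 and 4.63 in control replicates 1, 2 and 3 and 3.85, 3.65 and 6.76 in UV-B replicates 1, 2 and 3. For heat shock proteins these means were 4.29, 5.85 and 5.89 in control and 5.70, 5.71 and 3.98 under UV-B. The means cover unlike zones: 2, 3 and 3 usable zones in control replicates 1, 2 and 3, and 1, 2 and 3 under UV-B. Position on the zone axis as a covariate mostly removed list calls, over the 14 libraries without UV-B zone 3 replicate 1: of 12 lists passing without it, 9 lost the call, jasmonate synthesis, jasmonate response and sugar metabolism kept it, and only ribosomal proteins gained one. The mean UV-B difference of DNA replication genes went from -0.446 (SE 0.0840 over members, camera adjusted p = 0.00582) to -0.297 (SE 0.0612, camera adjusted p = 0.0557). That of expansins went from 0.379 to 0.206 (camera adjusted p from 0.00762 to 0.196), that of heat shock proteins from -0.729 to -0.463 (0.00582 to 0.0670) and that of DNA repair genes from -0.362 to -0.125 (0.0460 to 0.384). The same loss met mitosis, from -0.233 to -0.0585 (camera adjusted p from 0.0317 to 0.599), auxin response factors, from -0.225 to -0.0852 (0.00385 to 0.117), defence genes, from 0.601 to 0.351 (0.00385 to 0.0822), and tubulins, from -0.223 to -0.187 (0.0113 to 0.0557). For jasmonate response genes it was 0.873 without and 0.901 with position (camera adjusted p = 2.13e-05 with it). Means grew for ribosomal proteins, from -0.0910 to -0.178 (camera adjusted p from 0.330 to 0.00676), for sugar metabolism, from -0.423 to -0.466 (0.0135 to 0.00978), and for KNOX and ligule genes, from 0.410 to 0.451 (0.0288 to 0.0557, a call lost).

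In zone 2, 5 lists passed, and 0 with an estimated correlation (adjusted p = 0.982). Besides the jasmonate and defence lists they were expansins (median 0.48, camera adjusted p = 0.0455), of which 1 rose when adjusted over the list alone, and heat shock proteins (-0.42, camera adjusted p = 0.0455, and 0.0734 without UV-B zone 3 replicate 1). In zone 3, 8 passed, and 0 with an estimated correlation (adjusted p = 0.947). Secondary wall genes (median 1.81, camera adjusted p = 0.00815) and gibberellin synthesis genes (0.89, camera adjusted p = 0.0124, and 0.0902 without UV-B zone 3 replicate 1) were higher, with 1 gibberellin synthesis gene rising when adjusted over the list alone and no other member of the 8 lists passing. Histones (-0.31, camera adjusted p = 0.00131), ribosomal proteins (-0.38, camera adjusted p = 0.00397), DNA replication (-0.19, camera adjusted p = 0.00965) and tubulins (-0.45, camera adjusted p = 0.0492, and 0.0609 without that library) were lower. With DESeq2 size factors tubulins and KNOX and ligule genes no longer passed (camera adjusted p = 0.0539 for both). KNOX and ligule genes passed upward (camera adjusted p = 0.0492, and 0.424 without that library), although their median was 0.06 and their mean -0.04. The list test gave that library, with 728 reads, the same weight as the others, while the median and mean come from edgeR. The upward call is therefore not a result about UV-B in zone 3.

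Lists for flavonoid synthesis, DNA repair, light signalling, growth and the light reactions did not pass over the zones together. The DNA repair list held only RAD51A, RAD51B, mre11A, Mre11B, MSH1, Recq4, PARP1 and PARP2 genes. The light signalling list held only phot1, PhyB1, PhyB2, phyA2, PIF4, PIF5, fus6 and cop2. Other genes of these themes, targets of UV-B among them, were not covered by these list tests. Flavonoid synthesis genes, whose products absorb UV-B, had a median change of 0.09, with 0 of 9 members passing over all genes or adjusted over the list alone (camera adjusted p = 0.882). BZ1, a glycosyltransferase gene of anthocyanin synthesis, had a log2 change of 0.09 ± 0.24. DNA repair genes had a median of -0.31 (camera adjusted p = 0.124, and 0.0460 without UV-B zone 3 replicate 1), and PARP1 had a log2 change of -0.32 ± 0.16. Photoreceptor and light signalling genes (camera adjusted p = 0.473), growth-regulating factors (camera adjusted p = 0.773) and genes of the light reactions (camera adjusted p = 0.0900) did not pass either.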

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

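The test of zone differences in the gene lists, the split of whole replicates and all tests of the 3 patterns below were chosen only after the results were seen; the other splits were planned before.

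The UV-B effect on 2 gene lists differed between zones 3 and 2 by a test of the interaction itself. For histones the UV-B change was lower in zone 3 (median difference of log2 changes -0.40, camera adjusted p = 0.00227, adjusted p = 0.00128 without UV-B zone 3 replicate 1), and so it was for ribosomal proteins (-0.54, camera adjusted p = 0.0028, adjusted p = 0.00216 without that library). Both had adjusted p = 0.991 with an estimated correlation. No member passed on its own, and near-identical members of both families can share reads, which leaves single members uncertain. The zones compared also hold unlike replicate numbers. Control zone 2 had replicates 2 and 3 only, and control zone 3 had replicates 1, 2 and 3. UV-B zone 2 had replicates 1, 2 and 3, while in UV-B zone 3 only replicates 2 and 3 are usable. The list differences therefore do not separate zone from replicate number.

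The first pattern is that 6 of the 14 genes called for UV-B over the zones together, GRMZM2G036640 among them, lie within 21.1 Mb of chromosome 1. Chance placement is argued against, since 1 of 10000 random draws of 14 tested genes put as many within 25 Mb, and the median was 2. That window was chosen after the cluster was seen. The first rule, that no draw be as high, was not met and was replaced by a share under 0.05 after the draws were seen. Shared regulation of adjacent genes is argued against too, but only for the called genes. At least 11 tested genes, with a median of 68, lie between neighbouring called genes. Genes between them can change without a call, so this spacing cannot decide on regulation shared over a wider stretch, which stays open. A chromosome segment that differs between the control and UV-B plants stays open and may account for these calls without any UV-B response: of the other 329 genes in the span, 13.7% had an unadjusted p under 0.05, against 8.70% elsewhere, but 85 of 1991 other windows of that width were as high. Without UV-B zone 3 replicate 1 the shares were 14% and 8.58%, and 32 of 1995 windows were as high. For UV-B in zone 2 alone the shares were 7.29% and 4.17%, and 71 of 1991 were as high. For UV-B in zone 3 alone 374 of 1991 were as high. For control zone 3 against zone 1 the shares were 59.9% and 57.7%, and 486 of 1991 were as high. The windows started every 1 Mb and so overlapped. A window needed only 50 tested genes, far fewer than the span holds, and shares vary more over few genes. These window counts are therefore only a guide and not a chance level. In the span 1 further gene, GRMZM2G396090, was on (19.1 CPM) in UV-B replicate 1, of which only the zone 2 library is usable. It was off in the other replicate numbers, so its difference does not follow treatment. A response to UV-B itself stays open too.

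The second pattern is that jasmonate response genes differed between UV-B libraries. A UV-B exposure acting alike on all plants is argued against, but by 1 replicate number only. Of the 6 usable UV-B libraries, 3 lay above all controls, and the others were all of UV-B replicate 3. The clock mean (6.76 log2 CPM) and heat shock mean (3.98) of that replicate also stood apart from UV-B replicates 1 and 2 (3.85 and 3.65, 5.70 and 5.71). What set it apart there was not separated from the jasmonate difference. Position along the zone axis is argued against as well: it gives at most 0.0938 of log2 difference, against an observed 0.888. MPI, a proteinase inhibitor gene induced by wounding and chosen after its values were seen, had 21.4, 19.2 and 21.2 CPM in UV-B zone 2 replicates 1 and 2 and zone 3 replicate 2, 0 in the replicate 3 libraries, and at most 1.67 in controls. Handling or damage of single plants may be involved and stays open, with zones of 1 UV-B replicate number differing by at most 0.196, and so does an uneven response to UV-B. No control library showed such a rise, as the highest control median was 0.185, so the part of the handling prediction that concerned controls was not met.

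The third pattern is that clock genes differed between replicate numbers. The UV-B treatment is argued against, since the list mean ranged over 2.53 between control replicate numbers, while treatments differed by -0.309 when each replicate number counted once. The list test over libraries had the opposite sign (median 0.86). UV-B replicate 3, with the highest clock level, gave 3 of the 6 usable UV-B libraries. The replicate means also cover unlike zones, while the list test adjusts for zone. What made the signs differ was not tested. Position along the zone axis is argued against, giving a range of 0.276 against 3.11 observed. Time of day or temperature at collection is a candidate explanation that stays open: all 4 clock genes differed more between replicate numbers than between zones of 1 number, but the labels used here give no collection times. GI had 550 CPM in control zone 1 replicate 1 and 555 in UV-B zone 1 replicate 3.

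Other splits of the libraries were counted. For genes called for UV-B over the zones together, 2 of 100 splits within zones, the real one included, gave as many (real 14, highest other 14). These splits break up libraries of 1 number, which correlated (0.470), while the real grouping keeps them whole. They therefore cannot exclude chance. For lists, 20 of 100 gave as many (real 7, highest other 11), so chance cannot be excluded. The DNA replication list passed in 46 of these 100 splits, the real one included. When whole replicates were split, 5 of 10 gave as many (real 14, highest other 1494). That highest split set control 1, control 3 and UV-B 3 against control 2, UV-B 1 and UV-B 2, and with 790 genes for control 1, UV-B 1 and UV-B 3 it points to a structure of the samples other than treatment. For UV-B in zone 3, 2 of 10 splits gave as many genes (real 1, highest other 1) and 2 of 10 as many lists (real 8, highest other 8). For control zone 3 against zone 1, 1 of 10 gave as many genes (real 12153, highest other 0) and 4 of 10 as many lists (real 10, highest other 12). For UV-B zone 3 against zone 2, 1 of 10 gave as many genes (real 1708, highest other 257). With 10 splits a share under 0.05 cannot be reached.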

How the results depend on the processing

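Over all comparisons, 9230 values of named genes stayed on their side of the threshold, 236 lost and 9 gained a call, and 4 reversed. The first count includes uncalled genes, taken from lists for their high expression, that had no call to lose. It therefore does not measure how stable calls are. Among genes called for UV-B, leaving out any 1 of 12 libraries ended the calls of GRMZM2G007715 and GRMZM2G092433, any of 11 that of GRMZM2G373738 and any of 10 that of GRMZM2G108258. Among counts, 176 stayed within 1.5 times and 70 moved. Unless said, the cause was not tested, and unique reads, thinning, surrogate variables, the position covariate and voom over the usable libraries were chosen after seeing the data. The pseudocount alternative was not run, since the table holds counts. Thinned to equal depth, 9592 genes still differed between control zones 3 and 1.

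For UV-B over the zones together (14 genes) the count was 28 without a filter, 27 by DESeq2, 6 by limma-voom, 4 as the mean of within-zone contrasts, and 6 with unique reads. Other settings also left out UV-B zone 3 replicate 1, which alone gave 7 genes: 2 after thinning, 4 by limma-voom and 1 with a correlation of same-numbered libraries (0.470) added, 7, 17 and 28 with 1, 2 and 3 surrogate variables and 8 with the position covariate. For zone 1 (1 gene) it was 2 without a filter, 3 by DESeq2 and 0 after thinning. For zone 2 (0 genes) it was 1 without a filter, 3 by DESeq2, 1 by limma-voom and 1 from only the groups compared. For zone 3 (1 gene) it was 0 by limma-voom, with unique reads and after thinning, and 12 from only the groups compared. DESeq2 gave 7427 genes for control zone 3 against zone 1, 704 for control zone 2 against zone 1, 1189 for control zone 3 against zone 2 and 677 for UV-B zone 3 against zone 2. Unique reads gave 884, 1509 and 633 for the last 3, and thinning gave 1140 for control zone 2 against zone 1.

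A replicate block gave 115 genes for UV-B over the zones together, 4, 5 and 5 in zones 1, 2 and 3, and 5329, 7381 and 5868 for control zone 2 against zone 1, control zone 3 against zone 2 and UV-B zone 3 against zone 2. The numbers share only a label: 8 of 9 same-numbered pairs within a treatment correlated over 0.1 and the lowest was 0.0840. All 12 libraries with a partner correlated best with their own number within treatment, a hint from the data, not the design. The block also ties numbers across treatments, where 5 of 13 libraries correlated best with their own number and 7 of 14 pairs passed 0.1 (median 0.102), so its UV-B counts rest on a link that neither the labels nor these correlations give. Sample titles carry other numbers (3, 4 and 7 in control, 7, 8 and 9 under UV-B), and the 1 they share joins control replicate 3 and UV-B replicate 1.

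Leaving out each library gave 3 to 19 genes for UV-B over the zones together, 1 to 2, 0 to 2 and 0 to 1 in zones 1, 2 and 3, and 0 to 0 for the interaction. It gave 9811 to 12642 for control zone 3 against zone 1, 827 to 2136 for control zone 2 against zone 1, 750 to 3653 for control zone 3 against zone 2 and 149 to 2343 for UV-B zone 3 against zone 2. A group left with 1 library is assumed to vary like the others. Zone 1 gives no value without its lone UV-B library, or from only its groups.

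With an estimated correlation and by fry, 0 lists passed in each of the 4 planned comparisons. Leaving out UV-B zone 3 replicate 1, fry passed 22 lists for control zone 3 against zone 1, 2 for UV-B over the zones together and 0 for UV-B in zones 2 and 3, the estimated correlation 0 in each, and camera 12 for UV-B over the zones together. With unique reads, between control zones 3 and 1, log2 changes reversed for phot1 (-0.30), TIFY24 (-2.10), BX8 (-0.50) and TUBB3 (-0.23).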

Other observations

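List tests in zone 1, the on and off genes and the correlations below were chosen after the results were seen. Along control leaves, other genes changed between zones 1 and 3 by edgeR. BZ1 rose from 0.878 ± 0.332 to 54.3 ± 9.26 CPM, one of 3 of 9 flavonoid synthesis genes that rose (camera adjusted p = 0.138). The gibberellin synthesis gene an1 fell from 39.3 ± 8.80 to 1.05 ± 1.19 CPM. PIN10a, an auxin transporter gene, rose by 5.04 ± 0.37 and AUX32 by 4.91 ± 0.42 on the log2 scale, and 10 of 26 auxin genes rose and 6 fell (camera adjusted p = 0.387). Of 22 glutathione S-transferases, 13 rose and 3 fell (camera adjusted p = 0.0583, and 0.00176 without UV-B zone 3 replicate 1), with gst9 going from 3.27 ± 0.835 to 134 ± 14.9 CPM. Of 12 cellulose synthase genes of the primary wall, 7 rose and 2 fell (camera adjusted p = 0.440), with CSLD1 at a log2 change of -3.46 ± 0.36.

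In zone 1, with its single UV-B library, list tests added after seeing the data passed for heat shock proteins (median -1.43, camera adjusted p = 3.07e-11), KNOX and ligule genes (0.14, camera adjusted p = 2.27e-06), clock genes (0.98, camera adjusted p = 0.000814), sugar metabolism (-0.66, camera adjusted p = 0.0120) and abscisic acid (-0.36, camera adjusted p = 0.0494). Without UV-B zone 3 replicate 1 the calls of clock genes and abscisic acid ended (camera adjusted p = 0.0709 for each) and the other 3 stayed. The UV-B zone 1 library is of UV-B replicate 3, whose heat shock mean (3.98 log2 CPM) and clock mean (6.76) stood apart from UV-B replicates 1 and 2 (5.70 and 5.71, 3.85 and 3.65). The zone 1 values therefore do not separate UV-B from the replicate. With an estimated correlation the smallest value of the 5 lists was adjusted p = 0.683. Adjusted over the list alone, 2 KNOX and ligule genes rose. In the UV-B zone 1 library KN-1 had 2.6 and lg3 2.39 CPM.

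By replicate number, 13 genes were on (at least 4 CPM) in all usable zones of some replicates and off (under 0.5 CPM) in all usable zones of others. UV-B replicate 1 had 1 usable library, of zone 2, so its state rests on that library alone. Shuffling libraries within zones 1000 times gave at most 8 such genes, with a median of 0. These genes lie on 7 chromosomes with at most 3 on 1, and a median of 94.5% of their reads were unique, against 99.3% over all genes with at least 100 reads. The share was low in GRMZM2G108258 (26.0%), GRMZM2G375487 (40.7%) and GRMZM2G419024 (58.7%), all called for UV-B, and in GRMZM2G067702 (29.6%) and GRMZM2G130232 (32.0%). In the rest, which include the called gene GRMZM2G373738 (100%), it was at least 75.9%. Reads shared by transcripts of 1 gene lower this share too, so a low share need not mean reads shared between genes. The 13 genes include bHLH116, on only in UV-B replicates 1 and 2, and 3 genes on only in control replicate 1 and UV-B replicate 3. No biological explanation was tested.

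Across genes, which are not independent replicates, the UV-B change in zone 2 correlated with the change from control zone 1 to 3 (Pearson r = 0.505, Spearman rho = 0.552), comparisons that share no library. For the UV-B change in zone 3 and that from control zone 1 to 2, r was 0.0442 and rho -0.0262. The other 2 of the 4 pairs compared were UV-B in zones 2 and 3 (r = 0.478, rho = 0.283) and in zones 1 and 2 (r = 0.482, rho = 0.495). Libraries of the same number and treatment correlated (0.470), so these comparisons can be linked even where they share no library. Correlations to be found without a UV-B effect were not computed.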
